A study of Mus musculus with 12 samples.

How the data were processed

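Cortical RNA from 12 adult mice was profiled by poly(A) RNA-seq, with 3 libraries in each of 4 groups: knock-in with constitutive Grin1 exon 5 (KI), wild types of that line (KI_WT), exon 5 knockout (KO) and wild types of that line (KO_WT). Each library title carries its own animal number, so that replicates are separate animals. Numbers run from 93 to 101 and from 341 to 368, and the second range alone occurs in the knock-in line. In the knockout line KO 1, KO_WT 2 and KO_WT 3 are of the first range. The range is therefore partly confounded with genotype in KO against KO_WT, and with line between the wild types. Replicates within a group were numbered in the order of the sample records, and the numbers pair nothing.

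The authors demultiplexed with bcl2fastq 2.17 and aligned with STAR 2.5.0c to GRCm38, per the submitters' processing notes. Cufflinks 2.2.1 is named there as well, without its role. The read counter, gene annotation and strand setting were not given in the sources used here. Reads from overlapping or antisense genes can therefore have been assigned to either gene, and near-identical paralogs can have shared reads. The deposited table of raw counts holds whole numbers for 41388 Ensembl genes in 1 column per library. A deposited RPKM table from the authors holds the same genes and libraries. Count divided by RPKM gave the same length per gene in every library to within 0.0790% over 8288 genes (at least 500 counts and RPKM of at least 1), so the RPKM values carry the same information scaled by gene length and library total. Column names were matched to the library titles, and 0 columns were left unassigned. Of the gene IDs 40254 matched the GENCODE annotation of GRCm38 used for coordinates.

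Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups (17441 genes), libraries were scaled by TMM, and quasi-likelihood models with 1 mean per group were fitted to all 12 libraries, so that the groups shared 1 estimate of the spread (8 residual degrees of freedom; biological coefficient of variation 15.7%). The 5 comparisons were KI against KI_WT, KO against KO_WT, KI against KO, KI_WT against KO_WT, and the difference between the first 2. P-values were adjusted by Benjamini-Hochberg within a comparison with a threshold of 0.05. Levels are TMM-scaled CPM, and log2 fold changes are given with their standard errors or 95% intervals. Non-overlap means that the 3 libraries of one group all lay above the 3 of the other. Total counts were 31790970 to 36514024, and the 10 most abundant genes took 5.95% to 11.4% of them. Pairs of libraries within a group differed by 13.6 to 73.7 times the sampling variance, so no library was a copy of another.

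The fit was tested on simulated data drawn from the real means, library sizes and dispersions of the 17441 genes, with 200 genes changed. For KI against KI_WT 32.5% of genes changed 1.5-fold, 67% changed 2-fold and 90% changed 4-fold were called. For KO against KO_WT the shares were 26.5%, 67.5% and 92%, for KI against KO 33%, 68% and 87.5%, and for the wild types 23.5%, 66.5% and 93%. For the difference of effects they were 0%, 42% and 82.5%. Between 0 and 13 unchanged genes were called per run. The genes were drawn independently, without the variation that genes share between libraries. With fewer than 200 genes changed the adjustment is stricter, so the shares called would be lower.

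Gene lists (17 of pathways or complexes and 17 of cell types, regions and sex) were tested with camera from limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 34 lists within a comparison. Of the 55 calls with the preset correlation among 170 tests, 0 held with the estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone. For each of the 55 calls the median, the mean and the test had the same sign. Lists of 4 further groups (lysosome, nuclear respiratory chain, hypothalamus and pituitary) were made after the data were seen. Their camera p-values were adjusted over these 4 lists alone within a comparison, so they are not on the same footing as those of the 34. Genes were named by a rule. It takes Grin1, then up to 12 genes in each direction past the threshold whose libraries do not overlap. Where fewer than 10 pass, it adds the 5 higher and the 5 lower genes with the smallest p as values that did not pass. From each list it takes up to 3 members past the threshold over the list alone, or else the member with the smallest p. Some members that the rule takes are not reported here. Further list members, region markers and genes called by an alternative were chosen after their values were seen.

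Alternatives were RLE size factors, no count filter, at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom with quality weights, and limma on log2(RPKM + 0.1) or log2(RPKM + 1) for genes above 0.5 RPKM in at least 3 libraries. Others were a term for the animal number range, a term for Y-linked expression, the compared groups alone, the wild types of both lines as 1 control, and leaving out each library. The groups, comparisons, tests, gene lists, naming rule and these alternatives were fixed before the data were examined. Added after seeing the data were terms for olfactory bulb, thalamus and choroid plexus markers, fits without the 3 libraries highest in olfactory bulb markers or without the highest of each group (4 libraries), and list tests and the Grin2a and Grin2b values with each library left out. Exon usage was not analysed here.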

Results

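Poly(A) RNA from the cortex of adult mice on a C57Bl/6 background was sequenced in 12 libraries, each from its own animal. Grin1 encodes GluN1, the subunit shared by NMDA-type glutamate receptors, and exon 5 is an alternative cassette that adds a short segment to its extracellular amino-terminal domain. In the knock-in line exon 5 is constitutive (KI, 3 libraries) and in the knockout line it is removed (KO, 3 libraries). Each line has its own wild-type group (KI_WT and KO_WT, 3 libraries each). The libraries held 31790970 to 36514024 gene-assigned counts and 21927 to 22809 detected genes. The design asks what changes in the cortex when exon 5 is always present or always absent, and whether the lines respond differently.

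Grin1 (ENSMUSG00000026959; GRCm38 chromosome 2, 25291181 to 25319187, minus strand) was measured at similar levels in all 4 groups. Its TMM-scaled level was 311 ± 20.8 CPM (SD, n = 3) in KI and 319 ± 18.3 in KI_WT. It was 307 ± 35.7 CPM in KO and 333 ± 27.6 in KO_WT (SD, n = 3). By library the level was 334, 294 and 305 CPM in KI 1 to KI 3, and 333, 299 and 327 in KI_WT 1 to KI_WT 3. It was 269, 340 and 313 CPM in KO 1 to KO 3, and 363, 329 and 308 in KO_WT 1 to KO_WT 3. The log2 fold change was -0.04 (95% interval -0.26 to 0.18) for KI over KI_WT, with an edgeR adjusted p of 0.953. For KO over KO_WT it was -0.12 (95% interval -0.33 to 0.10), with an edgeR adjusted p of 0.771. With single libraries left out the latter was -0.19 (without KO 2) to -0.03 (without KO 1). A 63-bp coding exon of 21 codons at chromosome 2, 25311343 to 25311405, present in 4 of 8 annotated coding transcripts, has the length of the cassette; it makes up 1.473% of the longest transcript of 4276 bp. A gene-level count therefore cannot check the genotype labels.

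The other NMDA receptor subunits showed no call in any comparison. Grin2a, the subunit that rises as cortex matures, was at 12.2 ± 7.69 CPM in KO and 23.1 ± 1.82 in KO_WT (SD, n = 3), a log2 fold change of -0.92 (SE 0.43; edgeR adjusted p = 0.678). The lowest library was KO 1 with 3.75 CPM, and without it the log2 fold change was -0.49. Grin2b, prominent in early development, was at 375 ± 119 CPM in KO and 527 ± 14.6 in KO_WT (log2 fold change -0.49, SE 0.22; edgeR adjusted p = 0.678). KO 1 was again lowest with 253 CPM, and without it the log2 fold change of Grin2b was -0.27. In KI the corresponding log2 fold changes were -0.15 (SE 0.43) for Grin2a and 0.08 (SE 0.22) for Grin2b. Over the 5 comparisons the smallest camera adjusted p of the 6 measured subunits was 0.0884.

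**Figure D1:**
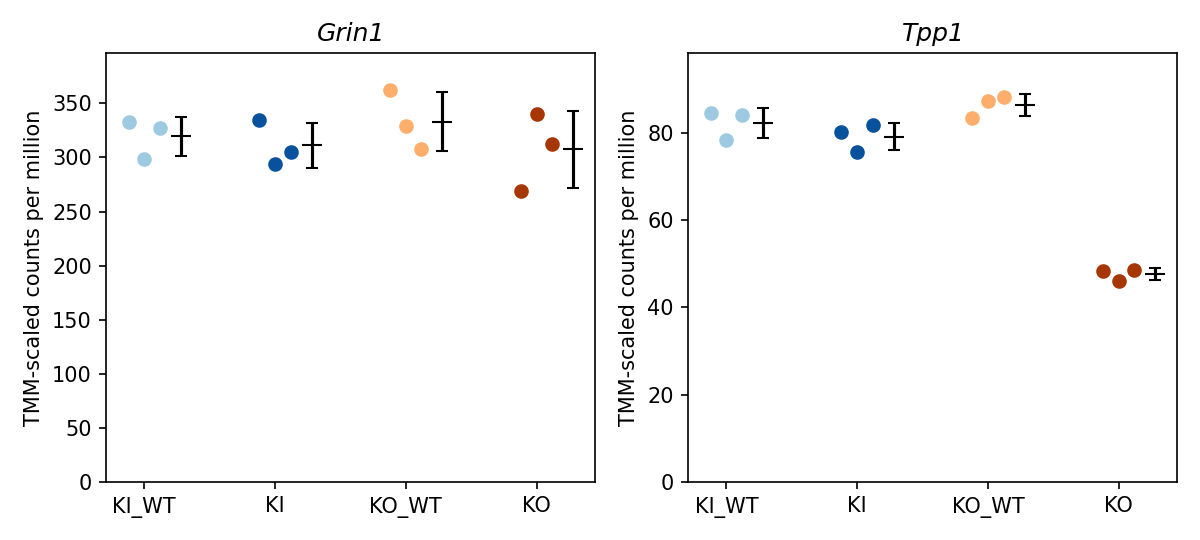
TMM-scaled CPM of Grin1 (left) and Tpp1 (right) in the 4 groups; points are libraries, bars are the mean ± SD of 3. Grin1 ranged from 269 to 363 CPM over all libraries, and Tpp1 lay between 46.1 and 48.6 CPM in KO against 75.6 to 88.2 in the other 9 libraries.

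Transcripts of neighbouring brain regions varied between libraries far more than Grin1 did. Ttr, the transthyretin transcript of choroid plexus, was at 2.36 CPM in KI_WT 3, 8.69 in KO_WT 1 and 8.85 in KO_WT 3, and at 513 to 1781 CPM in the other 9 libraries. Doc2g, an olfactory bulb transcript, reached 71.9 CPM in KI_WT 3, 26.5 in KO 1 and 26.5 in KO_WT 3, against 1.32 in KO_WT 1. Prkcd, abundant in thalamic relay neurons, was at 15.9 to 17.2 CPM in the KI_WT libraries and at 34.2 to 103 in the KI libraries. In the knockout line Prkcd was at 15.4 CPM in KO 1, 16.0 in KO_WT 1 and 13.5 in KO_WT 3, and at 56.3 in KO 2, 87.8 in KO 3 and 79.8 in KO_WT 2. Sex was not given in the labels. Xist, transcribed from the inactive X chromosome of females, was at 570 to 856 CPM in KI 2, KI 3, KI_WT 1, KO 1 and KO 2. It was at 0.0630 to 0.611 CPM in the others, so that all 3 KO_WT libraries were Xist-low.

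**Figure D2:**
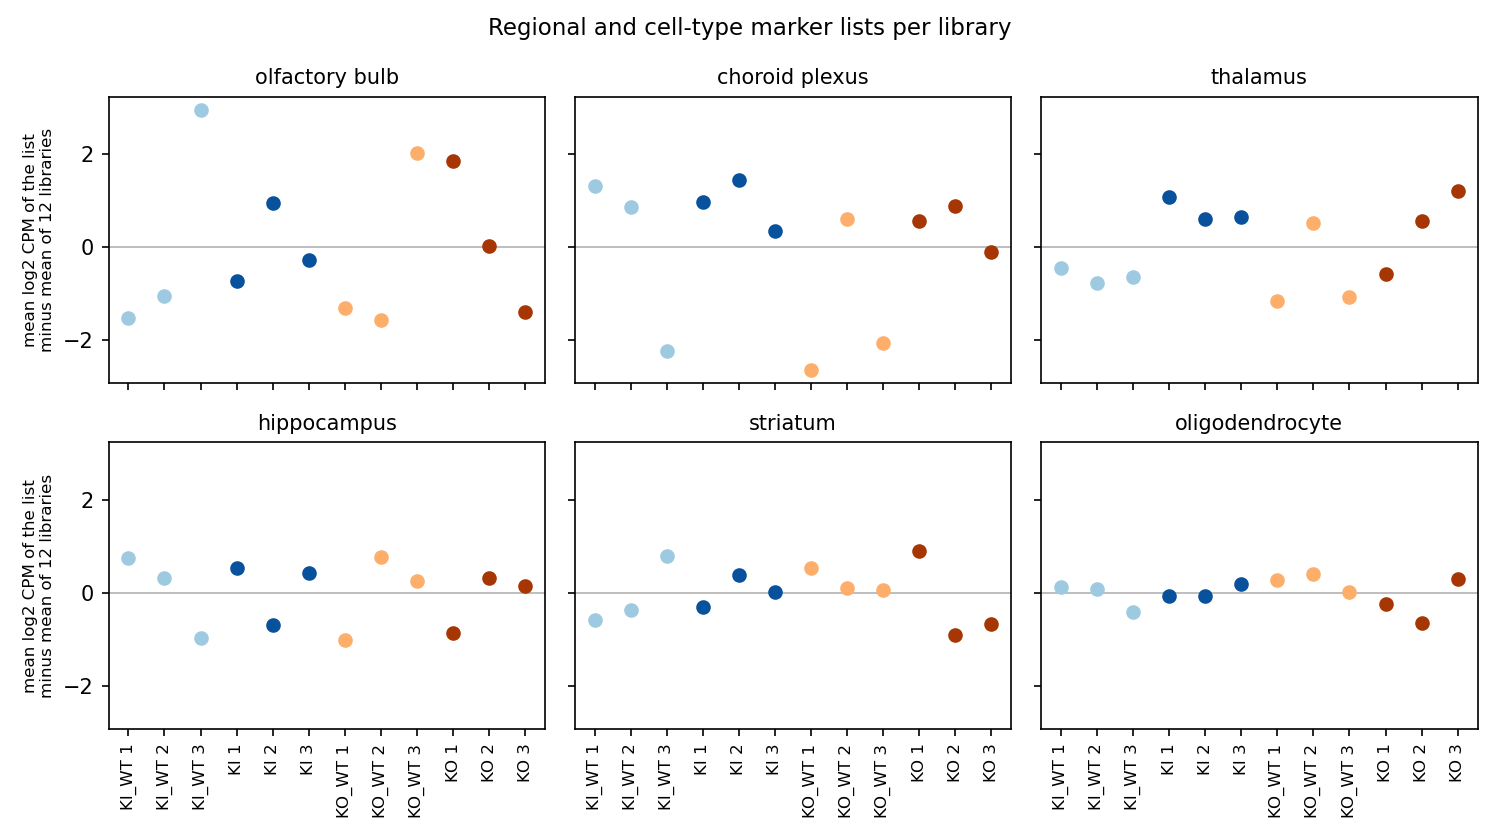
Mean log2 CPM of 6 marker lists in each library, relative to the mean of the 12 libraries; each point is 1 library, coloured by group. The olfactory bulb list spanned 4.53 log2 units and the choroid plexus list 4.09, and the KI libraries lay above the KI_WT libraries for the thalamus list.

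In the knock-in line, camera with a preset correlation called messenger RNAs encoded by the mitochondrial genome lower and thalamic transcripts higher in KI than in KI_WT, calls that an estimated correlation did not keep. Of 13 mitochondrially encoded genes 10 had a lower mean in KI, with a median log2 fold change of -0.55 (camera adjusted p = 2.3e-08, and adjusted p = 0.505 with an estimated correlation). They include mt-Co1, a subunit of cytochrome c oxidase, at 18701 ± 3035 CPM in KI and 27840 ± 5611 in KI_WT (SD, n = 3; log2 fold change -0.57, SE 0.15). The largest decrease was in mt-Nd4, a subunit of complex I, at -0.87 (SE 0.24). Libraries of the groups did not overlap for 3 genes of the list, against 12.2% of all tested genes. Adjusted over the list alone, 7 of the 13 passed, among them mt-Nd2 (-0.75), mt-Nd5 (-0.75) and mt-Cytb (-0.58); over all genes tested 0 passed. With terms for olfactory bulb, thalamus and choroid plexus markers in the model the median was -0.29, and with single libraries left out it was -0.63 to -0.37.

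Thalamus markers were higher in KI for 10 of 10 genes, with a median log2 fold change of 1.29 (camera adjusted p = 5.0e-15, and adjusted p = 0.446 with an estimated correlation). Of these 6 passed when adjusted over the list alone and 0 over all genes; they include Gbx2 (2.94, SE 0.66), a homeobox factor of thalamic neurons, and Prkcd (2.02, SE 0.71). Slc17a6, the vesicular glutamate transporter of subcortical neurons, was also higher at 0.58 (SE 0.20).

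Other lists called by camera in KI had smaller medians. Oligodendrocyte precursor markers had a median log2 fold change of 0.25 (7 of 8 higher), with an adjusted p = 0.505 with an estimated correlation. The 1 member past the threshold over the list alone was Olig1 (0.39, SE 0.098), a transcription factor of the lineage. Heat shock genes were higher for 18 of 20 members, with a median of 0.19; endoplasmic reticulum chaperone genes Creld2 (0.40, SE 0.15) and Sdf2l1 (0.54, SE 0.21) had the smallest p. For heat shock genes the adjusted p = 0.944 with an estimated correlation. GABA synapse genes were lower for 16 of 21 members (median -0.10; adjusted p = 0.845 with an estimated correlation). Voltage-gated channel genes were lower for 22 of 32 members (median -0.16; adjusted p = 0.944 with an estimated correlation). Chromosomal neighbours of Grin1 were higher for 27 of 34 members (median 0.07; adjusted p = 0.845 with an estimated correlation). Adjusted over each of these 4 lists alone, 0 members passed. Single libraries decided 4 of these calls, given here with the range of the median over all leave-outs. Voltage-gated channel genes (-0.21 to -0.06) and the neighbours of Grin1 (0.04 to 0.14) were not called without KI 2, KI_WT 1 or KI_WT 3. GABA synapse genes (-0.15 to -0.05) were not called without KI 2 or KI_WT 3, nor oligodendrocyte precursor markers (0.18 to 0.36) without KI_WT 3.

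No gene passed an adjusted p of 0.05 in KI against KI_WT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 17441 genes, the smallest adjusted p being 0.705. At an unadjusted p under 0.05 there were 1214 genes (531 higher and 683 lower), and DESeq2 and limma voom called 0. Libraries of KI and KI_WT did not overlap for 12.2% of genes, against 10% by chance. Among the genes with the smallest p were Lypd1 (log2 fold change 0.61, SE 0.13), whose product modulates nicotinic receptors, and Fign (0.75, SE 0.15). Atp5g2, a nuclear gene for the membrane ring of ATP synthase, was at -0.48 (SE 0.097). All 3 had an edgeR adjusted p of 0.705. Leaving out KI 1 or KI 2 moved the count at unadjusted p under 0.05 to 727 or 614, and leaving out KI 3 moved it to 1645. With limma voom it was 1730.

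**Figure D3:**
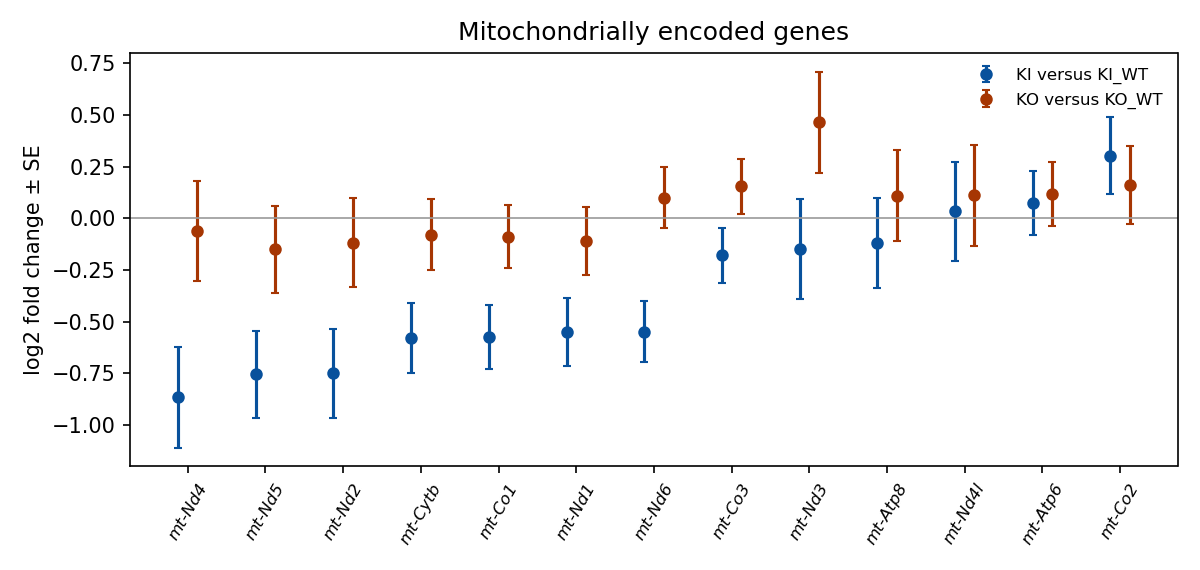
Log2 fold change ± SE of the 13 mitochondrially encoded protein genes in KI against KI_WT (blue) and in KO against KO_WT (brown), 3 libraries per group. In KI 10 of 13 lie below 0 and mt-Nd4 is lowest at -0.87; in KO 6 of 13 lie below 0.

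In the knockout line a lysosomal enzyme gene fell. Tpp1 (ENSMUSG00000030894; GRCm38 chromosome 7, 105744811 to 105752235, minus strand) encodes tripeptidyl peptidase 1, a lysosomal protease whose loss causes a childhood neuronal ceroid lipofuscinosis. It was at 47.7 ± 1.37 CPM in KO and 86.3 ± 2.55 in KO_WT (SD, n = 3), a fall to 0.553 of the wild-type level. The log2 fold change was -0.86 (SE 0.062, 95% interval -0.99 to -0.72), with an adjusted p of 1.71e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 3 KO libraries lay below the 3 KO_WT libraries; a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. Tpp1 was at 79.1 ± 3.13 CPM in KI and 82.3 ± 3.45 in KI_WT, a log2 fold change of -0.06 there.

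Tpp1 was the 1 gene called in KO against KO_WT by edgeR. At an unadjusted p under 0.05 there were 1260 genes (599 higher and 661 lower), and 12.4% of genes had libraries that did not overlap, against 10% by chance. DESeq2 called 5 genes, Tpp1, Xist, Ugt2a1, 1700048O20Rik and Abca9, and limma voom called Tpp1. Xist marks the sex of the animals. All KO_WT libraries were Xist-low and KO 1 and KO 2 were Xist-high, as given above, so sex was partly confounded with genotype in this comparison. The list tests were not run with the Y-linked term, so the list calls in KO below carry this limit. The DESeq2 log2 fold change of Ugt2a1 was 22.3, too large to read as a size of effect. Without KO 3 edgeR called 6 genes and 2636 at unadjusted p under 0.05; the 5 besides Tpp1 were lower and include Lrp4 (-0.78), a synaptic receptor for agrin, and Daam2 (-0.65). Without KO 2 or KO_WT 1 the unadjusted count was 766 or 781. It was 515 with a term for Y-linked expression and 1917 with one for the animal number range, both partly confounded with genotype here. With terms for regional markers edgeR called 0 genes (Tpp1 adjusted p = 0.0510), and the unadjusted count was 639. Of genes that did not pass, Abca9, a lipid transporter, had a log2 fold change of -0.45 (SE 0.086) and Slc17a6 one of 0.86 (SE 0.20), each with an edgeR adjusted p of 0.678.

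In KO camera with a preset correlation called ribosomal protein genes higher and postsynaptic density genes lower, and an estimated correlation kept neither call. The ribosomal list had a higher mean for 77 of 79 members, with a median log2 fold change of 0.13. Libraries did not overlap for 16 members, against 12.4% of all tested genes. The camera adjusted p was 9.0e-11, and the adjusted p = 0.461 with an estimated correlation. The list stood highest in KI_WT 2 (0.229 log2 units above the mean of all libraries) and KO 1 (0.213), and KO 3 was at -0.0732, within the -0.0989 to -0.0576 of KO_WT. Without KO 1 the median was 0.06. Postsynaptic density genes were lower for 30 of 33 members (median -0.14; adjusted p = 0.404 with an estimated correlation), with the scaffold genes Dlg2 at -0.57 (SE 0.16) and Homer2 at -0.45 (SE 0.14). Voltage-gated channel genes were lower for 28 of 32 (median -0.13; adjusted p = 0.449 with an estimated correlation), and GABA synapse genes for 16 of 21 (median -0.06; 0.461). Upper-layer neuron markers (median -0.24; adjusted p = 0.449 with an estimated correlation) and striatal markers (median -0.22; adjusted p = 0.654 with an estimated correlation) were also lower. Immediate early genes had a median of 0.13 and circadian genes one of -0.18; their adjusted p with an estimated correlation was 0.682 and 0.407. Adjusted over the list alone, 0 members of these 8 lists passed. The camera calls of ribosomal protein and postsynaptic density genes held with each library left out, and the other 6 rested on single libraries. Voltage-gated channel genes had a median of -0.05 without KO 1 and were not called. Immediate early genes turned to -0.09 without KO 1, and were not called without KO_WT 1 either. Circadian genes had a median of -0.06 without KO 2 and were not called. GABA synapse genes (-0.11 to -0.02 over all leave-outs) were not called without KO 2, KO_WT 1 or KO_WT 3. Upper-layer markers (-0.36 to -0.06) were not called without KO 2 or KO_WT 1. Striatal markers (-1.02 to 0.06) turned without KO 2 or KO 3, and were not called without these or KO_WT 1.

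Lists of glial and vascular markers were called lower in KO than in KO_WT with the preset correlation and not with an estimated one. Oligodendrocyte markers such as Mobp (-0.57, SE 0.26) and Mal (-0.53, SE 0.26) were lower for 12 of 12 members, with a median of -0.39 and an adjusted p = 0.407 with an estimated correlation. Per library the list lay at -0.651 in KO 2, -0.232 in KO 1 and 0.302 in KO 3 relative to the mean of all libraries, and at 0.0116 to 0.407 in KO_WT. Markers of oligodendrocyte precursors (8 of 8 lower, median -0.23), endothelium (10 of 10, -0.20), mural cells (8 of 8, -0.30) and astrocytes (9 of 12, -0.17) shared an adjusted p = 0.247 with an estimated correlation. Adjusted over the list alone, 2 precursor genes (Vcan and Gpr17), 2 endothelial genes (Flt1 and Abcb1a), 3 mural genes (Myh11, Abcc9 and Pdgfrb) and 0 astrocyte genes passed, and 0 of all these over all genes. Myh11, smooth muscle myosin, was at -0.66 (SE 0.16). Microglia markers were lower for 11 of 12 (median -0.06; adjusted p = 0.449 with an estimated correlation), with Csf1r, the receptor they need to survive, at -0.32 (SE 0.080) as the 1 member that passed over the list alone. Haemoglobin and other blood transcripts had a median of -0.36 (adjusted p = 0.461 with an estimated correlation). With single libraries left out the median was -0.69 (without KO 3) to -0.21 (without KO 2) for oligodendrocytes, -0.17 without KO 2 for mural cells and -0.15 without KO 1 for oligodendrocyte precursors, each still called by camera. Microglia markers (-0.04 without KO 3) were not called without KO 3, and blood transcripts (-0.53 to -0.08) were not called without KO 2 or KO_WT 3.

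Markers from outside the cortex went both ways in KO. Thalamus markers were higher for 10 of 10 members (median 0.64; adjusted p = 0.404 with an estimated correlation), and Slc17a6 and Gbx2 passed over the list alone. Choroid plexus markers were higher for 9 of 9 (median 0.995; adjusted p = 0.407 with an estimated correlation), with Ttr at 770 ± 234 CPM in KO and 273 ± 458 in KO_WT (SD, n = 3). Meningeal markers were higher for 9 of 10 (median 0.27; adjusted p = 0.510 with an estimated correlation). Adjusted over the list alone, 0 choroid plexus and 0 meningeal markers passed. With single libraries left out the median was 0.39 (without KO 3) to 1.20 (without KO_WT 2) for thalamus and 0.56 (without KO_WT 1) to 2.52 for choroid plexus. Meningeal markers (0.02 without KO 1) were not called without KO 1 or KO_WT 1. Besides the striatal markers, hippocampal markers lay lower without a call (9 of 12, median -0.23; camera adjusted p = 0.157).

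Set directly against each other, KI and KO differed in Tpp1. It was higher in KI, with a log2 difference of 0.73 (SE 0.062, 95% interval 0.60 to 0.87; 79.1 ± 3.13 against 47.7 ± 1.37 CPM, SD, n = 3) and an adjusted p of 9.98e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The KO libraries are those of the comparison with KO_WT, so the 2 results are not independent. The call was lost with the compared groups alone (edgeR adjusted p = 0.123) and without 4 libraries high in olfactory bulb markers (0.0649), where the range over all alternatives was 3.5e-24 to 0.123. At an unadjusted p under 0.05 there were 947 genes (318 higher and 629 lower in KI), and 10.2% of genes had libraries that did not overlap, against 10% by chance. Without KO 3 or KI 2 the unadjusted count was 1730 or 542, with Tpp1 as the 1 call in each.

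Mitochondrially encoded genes were again lower in KI when the reference was KO, which shares the KI libraries with the comparison above. Of 13 mitochondrially encoded genes 9 were lower (median -0.46), and adjusted over the list alone 7 were lower and 1, mt-Co2 (0.52, SE 0.19), was higher. The camera adjusted p was 7.3e-07, and the adjusted p = 0.473 with an estimated correlation. mt-Ts1, a mitochondrial serine transfer RNA, was at 0.782 ± 0.345 CPM in KI and 4.11 CPM in KO, with an edgeR adjusted p of 0.465. DESeq2 called 12 genes, 11 of them besides Tpp1 lower in KI. They include mt-Ts1, Atp5g2 (-0.52), the pyruvate carrier gene Mpc1 (-0.41), Apoo (-0.30) and Chchd10 (-0.42), the last a disease gene in motor neuron degeneration. A list of 84 nuclear respiratory chain genes, made after the data were seen, was not called here (40 higher and 44 lower, median -0.01; camera adjusted p = 0.347), with Atp5g2 and Ndufa12 past the threshold over the list alone. In the edgeR test Atp5g2, Mpc1, Apoo and Chchd10 each had an adjusted p of 0.811.

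Lists of vascular and oligodendroglial markers were called higher in KI than in KO with the preset correlation and not with an estimated one. Endothelial (10 of 10 higher, median 0.18), mural (8 of 8, 0.26) and oligodendrocyte precursor markers (8 of 8, 0.20) each had an adjusted p = 0.473 with an estimated correlation. Oligodendrocyte markers were higher for 12 of 12 (median 0.16; adjusted p = 0.830 with an estimated correlation). Myh11 (0.60, SE 0.16) and Acta2 (0.55, SE 0.19) of smooth muscle passed when adjusted over the list alone, with 0 members of the other 3 lists. Oligodendrocyte markers turned to -0.03 without KO 2, and were not called without KI 3, KO 1 or KO 2. Endothelial markers (0.16 without KO 2) were not called without KO 2, nor precursor markers (0.15 to 0.28 over all leave-outs) without KO 1. Mural markers had a median of 0.39 without KO 3.

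The wild-type groups of the lines were compared as a measure of how far the lines differ without the mutation. No gene passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.9998). At an unadjusted p under 0.05, 193 genes were higher and 148 lower in KI_WT. DESeq2 called 1, Ugt2a1, again with a log2 fold change too large to read (21.9), and limma voom called 0. Libraries did not overlap for 7.31% of genes, against 10% by chance. The unadjusted count was 663 without KI_WT 1, 587 with limma voom and 1160 with a term for the animal number range, which is partly confounded with line here. The KO_WT libraries are also those of the knockout comparison, so lists with the same sign in both are not independent results. Ribosomal protein genes were higher in KI_WT for 77 of 79 members (median 0.12; adjusted p = 0.595 with an estimated correlation), and choroid plexus markers for 9 of 9 (median 1.24; 0.471). Oligodendrocyte precursor markers were lower for 8 of 8 (median -0.27; adjusted p = 0.159 with an estimated correlation), with Gpr17 (-0.47) and Olig1 (-0.30) past the threshold over the list alone. Oligodendrocyte markers were lower for 11 of 12 (median -0.29; adjusted p = 0.471 with an estimated correlation). Ribosomal protein genes had a median of 0.02 without KI_WT 2 and oligodendrocyte markers one of -0.13 without KI_WT 3, and neither was called there. The median was 0.76 (without KI_WT 1) to 2.73 for choroid plexus and -0.16 without KI_WT 3 for precursor markers, both still called.

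Between the wild types camera called 11 further lists. Astrocyte (-0.13; adjusted p = 0.345 with an estimated correlation), microglia (-0.11; 0.471) and mural markers (-0.13; 0.595) were lower in KI_WT. So were postsynaptic density (-0.07; 0.753), AMPA receptor auxiliary (-0.10; 0.471), striatal (-0.17; 0.767), circadian (-0.10; 0.595), glucocorticoid response (-0.20; 0.471) and heat shock genes (-0.05; 0.767), each with its median and its adjusted p with an estimated correlation. Meningeal markers (0.22; 0.595) and immediate early genes (0.14; 0.781) were higher. Adjusted over each of these 11 lists alone, 0 members passed. Each of the 11 calls was lost without at least 1 library, given here with the range of the median over all leave-outs. For astrocytes (-0.15 to -0.11) it was KI_WT 3, for microglia (-0.19 to -0.08) KI_WT 1 or KI_WT 3, and for mural cells (-0.17 to -0.04) KO_WT 1 or any KI_WT library. For glucocorticoid response (-0.35 to -0.10) it was KI_WT 2, for circadian genes (-0.16 to -0.03) and meninges (0.12 to 0.31) KI_WT 2 or KO_WT 1, and for the postsynaptic density (-0.09 to -0.02) KI_WT 2, KI_WT 3 or KO_WT 1. For AMPA receptor auxiliary genes (-0.17 to -0.07) it was any library but KO_WT 2. Immediate early genes (-0.05 to 0.30) turned without KI_WT 3, and were also not called without KI_WT 1, KO_WT 1 or KO_WT 3. Heat shock genes (-0.15 to 0.01) turned without KI_WT 2 or KO_WT 2, and were also not called without KI_WT 1 or KO_WT 3. Striatal markers (-0.71 to 0.06) turned and were not called without KI_WT 1, KI_WT 2 or KO_WT 1.

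The difference between the genotype effects of the lines, KI over KI_WT against KO over KO_WT, was tested as an interaction. Tpp1 was the 1 gene called, with a difference of 0.80 on the log2 scale (SE 0.087, n = 3 per group) and an adjusted p of 0.0155 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 918 genes. Next by p was Lypd1, 114 ± 12.4 CPM in KI, 74.3 ± 7.99 in KI_WT, 85.5 ± 15.1 in KO and 105 ± 2.76 in KO_WT (SD, n = 3). Its difference was 0.91 (SE 0.18), with an edgeR adjusted p of 0.918. The 5 lower genes with the smallest p were Atp5g2 (-0.69, SE 0.14), Apoo (-0.43, SE 0.088), A430106G13Rik (-1.52, SE 0.32), Cox7b (-0.47, SE 0.11) and 2810055G20Rik (-0.75, SE 0.18), at the same edgeR adjusted p of 0.918. DESeq2 called 5 genes, Tpp1, Lypd1, Ugt2a1, Atp5g2 and Apoo, where the difference of Ugt2a1 (-27.5) was again too large to read as a size of effect. The Tpp1 call was lost in edgeR without KI 1 (adjusted p = 0.0691), KI 3 (0.0647), KI_WT 1 (0.0578), KI_WT 2 (0.0616), KO_WT 2 (0.0819) or KO_WT 3 (0.0869), with log2 differences of 0.76 to 0.83 over all leave-outs. It was also lost with the Y-linked term (edgeR adjusted p = 0.0800), with regional terms (0.298), and without 3 (0.211) or 4 (0.260) libraries high in olfactory bulb markers, where the range over all alternatives was 2.8e-13 to 0.298. Without KO 3 the count at unadjusted p under 0.05 was 1605.

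Of the 34 lists, oligodendrocyte precursor markers had the smallest camera adjusted p for the difference between the lines (6.5e-09), with 8 of 8 members higher in the KI effect (median 0.46; adjusted p = 0.158 with an estimated correlation). Larger medians without a call were those of olfactory bulb (-1.50), choroid plexus (-0.84), thalamus (0.79) and blood (0.50). Of the precursor markers 4 passed when adjusted over the list alone, Olig1 (0.55), Gpr17 (0.78), Cspg4 (0.65) and Pdgfra (0.64). Oligodendrocyte (median 0.49; adjusted p = 0.508 with an estimated correlation), microglia (0.15; 0.444), endothelial (0.24; 0.426), mural (0.43; 0.426) and astrocyte markers (0.19; 0.426) differed in the same direction. So did postsynaptic density (0.12; 0.766) and circadian genes (0.17; 0.627). Mitochondrially encoded genes (-0.49; 0.426) and ribosomal protein genes (-0.16; 0.771) differed in the opposite direction, the values again being the median and the adjusted p with an estimated correlation. Csf1r (0.46) and Myh11 (0.89) passed over the microglia and mural lists alone, with 0 members of the remaining 7 lists. Without KI_WT 2 the median was -0.05 for ribosomal and -0.30 for mitochondrially encoded genes, and without KO 2 it was 0.29 for oligodendrocytes, all still called. Microglia markers had a median of 0.10 (without KO 3) to 0.23 over all leave-outs and stayed called. Calls were lost for astrocytes without KI 1, KI_WT 3 or KO 1 (0.10 to 0.21 over all leave-outs), for endothelium without KO 2 (0.18 to 0.37) and for the postsynaptic density without KO 1 or KO_WT 1 (0.05 to 0.21). Circadian genes (0.04 to 0.32) were not called without KI 3, KI_WT 2, KO 1, KO 2 or KO_WT 1. The interaction also holds the difference between the wild types. For precursor markers the median was 0.20 in KI against KO and -0.27 in KI_WT against KO_WT. Oligodendrocyte, microglia, mural, astrocyte, postsynaptic density, circadian and ribosomal lists were likewise called between the wild types, with the opposite sign. Endothelial and mitochondrially encoded genes were not.

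A likeness of the genotype effects across genes was not told apart from none. Over 17441 genes Pearson's r between the differences of mean log2 CPM in the lines was 0.269 and Spearman's rho was 0.146, and on the fold changes fitted by edgeR r was 0.118; genes are not independent replicates. An exact permutation of the genotype labels within each line (400 labellings, two-sided, smallest possible p = 0.01) gave p = 0.21 for r and p = 0.4 for rho. Among genes with a mean log2 CPM above 5 r was 0.290 (exact p = 0.32). Over these 3 relations the exact p adjusted by Benjamini-Hochberg was 0.4 for each. Without KI 2 r was 0.146 and without KI_WT 3 it was 0.156. At an unadjusted p under 0.05 in both lines there were 99 genes, 71 with the same and 28 with opposite direction, where independent lists would share 87.7.

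**Figure D4:**
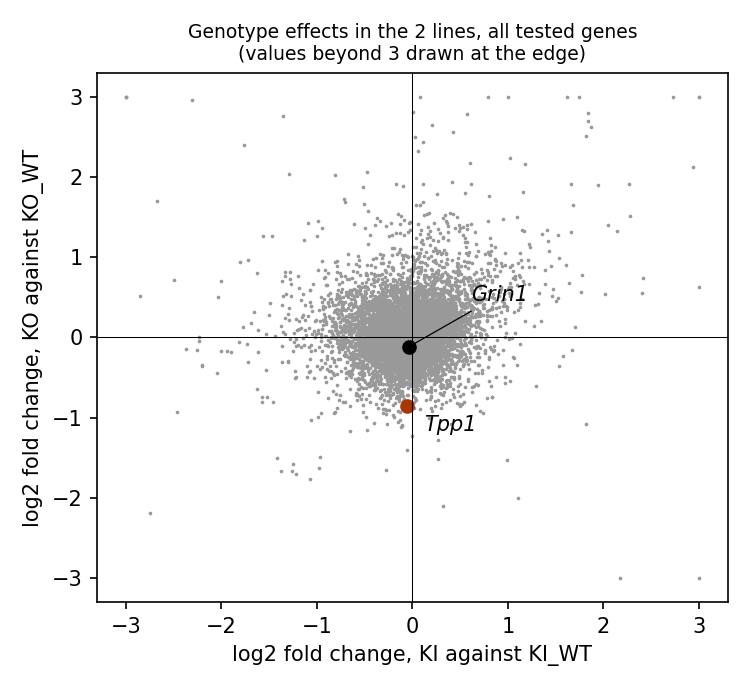
Log2 fold changes of 17441 genes in KI against KI_WT (horizontal) and KO against KO_WT (vertical), with Grin1 in black and Tpp1 in brown; 13 genes beyond 3 are drawn at the edge. Tpp1 lies at -0.86 in KO and -0.06 in KI.

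Genes around Grin1 were examined because targeted alleles carry flanking DNA of the embryonic stem cells. Of 34 annotated neighbours and of 162 genes within 5 Mb, 0 were called by edgeR in each of the 5 comparisons, where 0 or 1 genes called elsewhere leave nothing to compare. At an unadjusted p under 0.01 there were 0 to 1 neighbours and 0 to 2 genes within 5 Mb, with a smallest Fisher's exact p of 0.244. The neighbours as a list were called higher in KI by camera, as given above (27 of 34; adjusted p = 0.0149, and 0.845 with an estimated correlation). Mrpl41, a mitochondrial ribosomal protein gene, passed over the neighbour list alone in KO (0.26, SE 0.064). Nnt, which carries a deletion in some C57BL/6 colonies, was at 19.0 to 19.6 CPM in the group means.

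The remaining lists were called in no comparison. Their smallest camera adjusted p over the 5 comparisons was 0.157 for AMPA, kainate and delta receptor subunits, 0.212 for metabotropic glutamate receptors and 0.157 for presynaptic release genes. It was 0.0987 for neuronal splicing regulators, 0.106 for C57BL/6 substrain markers, 0.300 for deep-layer neurons, 0.485 for interneurons, 0.157 for hippocampus, 0.275 for olfactory bulb and 0.138 for sex-linked genes. The sex-linked list joins Xist with Y-linked genes, which go opposite ways between the sexes. Its test partly cancels and does not show that the sexes were balanced.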

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

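The tests of Tpp1 with regional terms, with the Y-linked term and of its gap between libraries, the tests of the mitochondrial genes with 1 library left out and against nuclear genes, and the test of the lists with an estimated correlation were chosen after the results were seen. For the regional and Y-linked terms the deciding bound was first an adjusted p under 0.05, and was replaced, once both values were known, by a 95% interval that stays below a log2 fold change of -0.4.

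Tpp1 is taken up here because the genotype effects of the lines differed in it by a test of the difference itself: 0.80 on the log2 scale (SE 0.087; edgeR adjusted p = 0.0155, range over its alternatives 2.8e-13 to 0.298). It was 0.553 of the wild-type level in KO. The tables argue against some explanations and limit another. A chromosome 7 segment that changes many genes around Tpp1 would raise the share of genes with p under 0.05 within 5 Mb. That share was 4.21% of 95 genes (exact 95% interval 1.16 to 10.4) against 7.24% elsewhere (Fisher's exact p = 0.322). This speaks only against a share above 10.4%. A smaller rise, or changes too small to reach that p, was not excluded. The median absolute log2 fold change was 0.140 within 5 Mb and 0.121 elsewhere. Sex is argued against by a log2 fold change of -0.853 with the Y-linked term (edgeR adjusted p = 0.00467). Lysosomal genes lowered together are argued against by a median of 0.0139 over 38 other lysosomal genes. Its bootstrap 95% interval of -0.0340 to 0.0563 resampled genes, so it leaves out the spread between animals. By library the mean of the list spanned 0.0870 log2 units over all libraries.

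Tissue of other brain regions is argued against by the size of the effect, under the bound set once the values were known. By the first bound, an adjusted p under 0.05, it was not argued against. With terms for regional markers the log2 fold change was -0.877 (95% interval -1.09 to -0.66) against -0.86 without them; the standard error rose from 0.062 to 0.0963, and the edgeR adjusted p of 0.0510 (range over the alternatives 1.2e-33 to 0.0510) ended the call through that error. Among the KO libraries the olfactory bulb list ran from -1.39 to 1.86 and the thalamus list from -0.582 to 1.22, while Tpp1 stayed at 46.1 to 48.6 CPM. The genotype of the knockout line stays open. The highest KO library lay 0.637 log2 units below the lowest of the other 9, a separation that the loss of exon 5 could give. A variant near Tpp1 that the KO animals share could give it too, and the design confounds these. How exon 5 would act on Tpp1 was not tested.

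Mitochondrially encoded messenger RNAs had a median log2 fold change of -0.547 in KI against KI_WT. The mean over the list was -0.36. By library the list lay at -0.237, -0.386 and -0.0552 in KI 1 to KI 3, relative to the mean of all libraries. In KI_WT 1 to KI_WT 3 it lay at 0.0779, 0.441 and -0.144, so the groups overlapped. A single library as the whole cause of the lower median is argued against by the median closest to 0 with 1 of the 6 left out, -0.369 (without KI_WT 2). The mean of the list, in which KI_WT 2 stood highest at 0.441, was not tested in this way. KI_WT 2 as a large part of the difference was therefore not excluded. A lower level of respiratory chain transcripts from both genomes is argued against by the nuclear respiratory chain list, with a median of 0.0418. Tissue of other regions stays open: with regional terms the median was -0.292 and the median standard error rose from 0.186 to 0.224. The genotype of the knock-in line may contribute and was not separated from this.

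Of the 55 list calls with a preset correlation, 0 hold with an estimated correlation, as they would if the genes of a list vary together between libraries. Differences in the tissue taken and in cell composition are a candidate source of such co-variation; with regional terms camera called 48 lists, 30 of them among the 55. Other splits of the same libraries point to a structure of the samples. Setting KI_WT 3, KO_WT 1 and KO_WT 3, the libraries low in Ttr, against the other 3 wild types called 41 genes, where the real split called 0. Setting KO 1, KO_WT 1 and KO_WT 3, low in thalamus markers, against the other 3 of the knockout line called 9, where the real split called 1.

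For comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. The numbers of splits given here include the real one. At least as many genes as in the real split were called by edgeR in 10 splits for KI against KI_WT (real 0, highest other 0), with 1214 genes at unadjusted p under 0.05 and 0 by DESeq2. The number was 2 for KO against KO_WT (real 1, highest other 9) and 2 for KI against KO (real 1, highest other 1). It was 10 for the wild types (real 0, highest other 41), with 193 genes higher and 148 lower at unadjusted p under 0.05 and 1 by DESeq2. Where the real split called 0, every split gives at least as many, so these numbers of 10 were fixed beforehand and decide nothing. For the difference of effects 7 of 50 splits gave as many (real 1, highest other 12), so chance was not excluded for that count.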

How the results depend on the processing

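The alternatives with regional terms, without 3 or 4 libraries, and the list tests with single libraries left out were chosen after seeing the data. No paired analysis was possible because replicates are numbered in the order of the records and each title carries its own animal number.

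The number of genes called kept its value in 19 of 20 alternatives for KI against KI_WT, 15 of 20 for KO against KO_WT, 15 of 19 for KI against KO, 17 of 19 for the wild types and 13 of 24 for the difference of effects. The correlation of effects kept its direction in 13 of 13. KI against KI_WT had 1 call with the compared groups alone (Abhd12b, 3.43, edgeR adjusted p = 0.0199), where the spread is estimated from fewer samples. KO against KO_WT had 5 with DESeq2, 0 with regional terms, 2 without 3 libraries (Tpp1 and Lrrc10b, -1.30), 3 without 4 libraries (also Gpr151, 2.87), and 1 to 6 with single libraries left out (6 without KO 3). KI against KO had 2 without a filter (Tpp1 and mt-Ts1, -2.38), 12 with DESeq2, 0 without 4 libraries and 0 with the compared groups alone. The wild types had 1 call with DESeq2 and 1 with the compared groups alone. The difference of effects had 5 with DESeq2, 0 with the Y-linked term, 0 with regional terms, 0 without 3 libraries, 0 without 4 libraries, and 0 to 1 with single libraries left out (0 without KI 1, KI 3, KI_WT 1, KI_WT 2, KO_WT 2 or KO_WT 3). At unadjusted p under 0.05 edgeR had 1260 genes in KO against KO_WT, 947 in KI against KO and 918 in the difference. Beyond the fewer samples named, the cause was not tested.

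Tpp1 in KO against KO_WT was past the threshold in 19 of 20 alternatives (log2 fold change -0.88 to -0.76; adjusted p 1.2e-33 to 0.0510, lost with regional terms). In KI against KO it was past it in 17 of 19 (0.70 to 0.77; adjusted p 3.5e-24 to 0.123), and lost with the compared groups alone (0.123) and without 4 libraries (0.0649). In the difference it was past it in 14 of 24 (0.75 to 0.83; adjusted p 2.8e-13 to 0.298). There it was lost with the Y-linked term (0.0800), regional terms (0.298), without 3 libraries (0.211), without 4 libraries (0.260) and in the 6 leave-outs named above. The 55 list calls fell to 0 with an estimated correlation; with single libraries left out camera called 51 to 72, of which 41 to 54 were among the 55.

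Grin1 reversed direction around 0. For KI against KI_WT its log2 fold change was 0.0127 with log2(RPKM + 0.1), 0.0123 with log2(RPKM + 1), 0.0151 without 4 libraries and -0.0845 to 0.0016 with single libraries left out. For KI against KO it was -0.0547 with the cohort term, -0.0622 without 3 libraries, -0.0311 without 4 libraries and -0.0621 to 0.1011 with single libraries left out. For the wild types it was 0.0308 with regional terms and -0.1063 to 0.0092 with single libraries left out. For the difference it was -0.0183 with regional terms and -0.0020 to 0.1613 with single libraries left out. The cause was not tested. P-values of edgeR and of the permutations of labels measure spread between animals. Fisher's exact tests take genes as units. Camera with the preset correlation allows little for genes that vary together between libraries. At the depth of 31790970 to 36514024 counts, 17441 genes could be tested, and in simulated data 26.5% of 1.5-fold changes were called in KO against KO_WT.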

Other observations

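Hypothalamic peptide transcripts were present in some of the cortical libraries; these lists and genes were chosen after the data were seen. Pmch, which encodes melanin-concentrating hormone, was at 69.5 CPM in KO 1, 44.5 in KI 1, 28.1 in KI 2 and 8.49 in KO 2, and at 0.120 to 1.77 in the other libraries. Hcrt, the orexin precursor, was at 20.6 CPM in KO 1, and Oxt, the oxytocin precursor, at 35.5 in KI 1 and 31.8 in KO 1. A hypothalamus list of 11 genes had a median log2 fold change of 1.62 in KI against KI_WT (10 higher) and 2.23 in KO against KO_WT (11 higher); the camera adjusted p was 0.369 and 0.267 with an estimated correlation. Between the wild types the list was also higher in KI_WT than in KO_WT (11 of 11, median 1.07; camera adjusted p = 0.0157, and 0.457 with an estimated correlation). Prl, a pituitary hormone gene, was at 23.5 CPM in KI_WT 1 and 18.7 in KO 1, and below 1 CPM in the other libraries; Gh was at 4.56 and 5.37 in the same libraries.

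Nuclear genes of the respiratory chain were higher in KO than in KO_WT for 83 of 84 members, with a median log2 fold change of 0.16. Libraries did not overlap for 37 of them, against 12.4% of all tested genes. Genes that vary together between libraries are not separate results, so this number is not one of independent genes. The camera adjusted p was 6.6e-20 (0.267 with an estimated correlation). The same list was higher in KI_WT than in KO_WT for 80 of 84 members (median 0.13; camera adjusted p = 0.302 with an estimated correlation), with KO_WT shared by these comparisons. In KI against KI_WT the median was 0.04 (camera adjusted p = 0.446) and in KI against KO it was -0.01 (0.347). In the difference of effects 70 of 84 members were lower (median -0.15; camera adjusted p = 2.4e-10, and 0.494 with an estimated correlation), and Atp5g2 and Cox7b passed over the list alone. The list had its lowest level in KO_WT 1 (-0.165 log2 units from the mean of all libraries) and the highest in KO 1 (0.189). Over the 5 comparisons the smallest camera adjusted p, adjusted over the 4 added lists alone, was 0.0513 for the pituitary list and 0.0899 for the lysosome list.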
